A study of Homo sapiens with 2 samples.

How the data were processed

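E2F1-bound chromatin was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in LNCaP cells, an established androgen-responsive human prostate cancer line. The 2 libraries came from a line with a short hairpin against the retinoblastoma tumour suppressor RB (shRB) and from a line with a control hairpin (shCON), 1 library each. Per the labels, both were kept for 72 h in CDT before harvest, and the series describes this as a hormone-deficient condition. A pair of E2F1 antibodies is listed for each sample.

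The deposited files were 1 peak list per library with 5 columns and no header: chromosome, start, end, peak name and a score. The submitters' processing notes name Bowtie, MACS2 and the hg19 genome build, without versions or settings, and the peak names mark each list as called on a single library. The threshold, the control library used for calling and any filter on repeats are not given in the sources used here. The score is the authors' peak score, as deposited. Its scale is not stated, and its lowest value was 2.02 in the shRB list and 2.15 in the shCON list. Scores were therefore used only to rank peaks within their own list. The shCON peak names carry a date and the shRB names do not, so whether both libraries were made and sequenced together is not known.

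Read counts, read depth and signal between the peaks were not analysed here. The depth behind each peak is unknown, and a difference in depth or in enrichment between the libraries could change the number, width and score of peaks. With 1 library per line there was no replicate spread and no test between the lines. Percentages carry a 95% Wilson interval, peak numbers an exact Poisson interval, the ratio of peak numbers a normal interval on the log scale and medians an interval from binomial order statistics. All of these cover counting over peaks only, and neighbouring peaks are not independent.

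A peak was called shared when it overlapped a peak of the other list by at least 1 bp (bedtools 2.31.1), and shRB-only or shCON-only otherwise. Chance overlap was measured by 100 seeded random placements of one list on the same chromosomes, within the span of the peaks and with each peak's width kept. Score deciles and the upper 25% of a list held equal numbers of peaks, with ties ordered by position. The shRB-only share expected on a chromosome was the mean of the genome-wide share in each peak's score decile. Peaks per Mb refer to the stretch from the first to the last peak of either list on that chromosome. Starts were converted from 0-based to 1-based coordinates on hg19. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The overlap, distance, placement and decile functions passed 12 of 12 checks. Most of these used planted or randomly placed positions built on 26431 simulated peaks. The others compared bedtools with a separate numpy routine on the deposited lists, and checked that deciles held equal numbers.

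Before the data were examined, the groups, the tests, the alternatives and the rule for named peaks were fixed. The plan also held gene lists, promoter shares and motif counts. These 4 results were not made, because the annotation at hand was of another build (GRCh38) and no hg19 sequence was used here. Peaks are accordingly named by position, without genes: the rule took the 5 highest-scoring peaks of each overlap class. The lists fixed for cell cycle, DNA repair, androgen receptor, neuroendocrine and other genes gave no result for the same reason. The alternatives were the upper 50% of each list by score, equal numbers from the top of each list, chromosomes 1 to 22 and X only, a reciprocal overlap of 50%, centres within 200 bp, and an extension of the other list by 500 bp. The comparisons of width at matched score, of paired peaks, of distances, of peak-free stretches, of 1 Mb windows and of chromosome shares against score were chosen after the lists had been seen.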

Results

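E2F1 is a transcription factor that drives genes of DNA replication and cell-cycle entry, and RB is the repressor that binds it. The series asked how the sites bound by E2F1 differ once RB is depleted in LNCaP prostate cancer cells deprived of hormone for 72 h. The data were 2 lists of E2F1 peaks, 1 from the RB-depleted line (shRB) and 1 from the control line (shCON). No count of reads was used, so the depth behind the lists is unknown. Each line had 1 library, so the differences have no replicate check, and the level of RB itself is not part of these data.

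More of the genome was called E2F1-bound in the RB-depleted cells. The shRB list held 26431 peaks (95% Poisson interval 26113 to 26752) and the shCON list 11653 (11442 to 11867), a ratio of 2.27 (2.22 to 2.32). The shRB peaks covered 13.9 Mb and the shCON peaks 4.43 Mb, a ratio of 3.14. The ratio of lengths exceeded the ratio of numbers because single peaks were also wider in shRB, with a mean width of 525 bp against 380 bp in shCON. The median width was 438 bp (interval 432 to 443) in shRB and 344 bp (341 to 348) in shCON.

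By an overlap of at least 1 bp, most peaks called in the control line were also called in the RB-depleted line. Many shRB peaks had no call in shCON, which is not absence of binding there. Of the 11653 shCON peaks, 10527 overlapped a shRB peak, or 90.3% (Wilson interval 89.8 to 90.9). Of the 26431 shRB peaks, 10139 overlapped a shCON peak, or 38.4% (37.8 to 38.9), and 16292 did not. As the numbers of overlapping peaks were similar, the lower shRB share largely follows from the longer shRB list. The remaining 1126 shCON peaks, 9.66% (9.14 to 10.2), had no shRB counterpart. Merging both lists gave 27540 regions, of which 10122 were called in both lines, 16292 in shRB only and 1126 in shCON only. Randomly placed shRB peaks overlapped a shCON peak in 0.462% of cases on average and in at most 0.586% over 100 placements. For randomly placed shCON peaks the mean was 1.05% and the highest value 1.28%. Both observed shares were thus far above uniform placement over each chromosome's span. Such placement includes stretches without peaks and does not allow for both lists lying in the same peak-rich regions, so it is a low bar. With a reciprocal overlap of 50% the shares with a partner were lower, at 52.0% (51.1 to 52.9) of shCON peaks and 22.9% (22.4 to 23.4) of shRB peaks. When the shRB list alone was cut to its 11653 strongest peaks, 76.7% (75.9 to 77.4) of them overlapped a shCON peak and 2720 did not. That cut removes low-scoring shRB peaks, few of which had a partner, so a higher share follows from it. With the upper 50% of each list by score, the shares were 40.2% of shRB and 91.9% of shCON peaks.

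The peaks called only in RB-depleted cells mostly had lower scores than the shared ones. The median score of shRB-only peaks was 12.6 (interval 12.4 to 12.8) and that of shared peaks in the same list 65.9 (65.3 to 66.8). In the lowest score decile of the shRB list 1.59% of peaks (1.18 to 2.14) were also found in shCON, in the seventh decile 54.4% (52.5 to 56.3), and in the highest 99.6% (99.3 to 99.8). Only 10 of the 2644 peaks in the highest decile were absent from shCON. The lowest 5 deciles held 12373 of the shRB-only peaks, or 75.9%, and the upper 25% of the list by score held 420. In the shCON list the dependence on score was shallower, with less room for it, since 90.3% of that shorter list was shared. There, 76.2% (73.7 to 78.6) of the lowest decile and 99.1% (98.3 to 99.5) of the highest were found in shRB. The median score was 7.83 (7.49 to 8.04) for shCON-only peaks and 13.5 (13.2 to 13.8) for shared peaks of that list. Scores are the authors' own peak values and were compared only within a list.

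**Figure D1:**
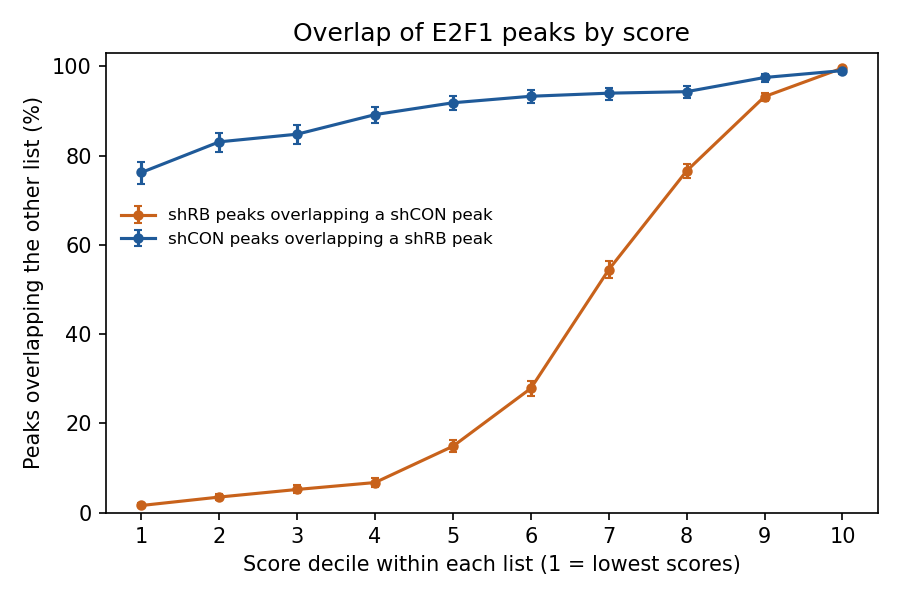
Share of peaks (%) that overlap the other list by at least 1 bp, against the score decile within each list, for the shRB list (orange) and the shCON list (blue), with 95% Wilson intervals. The shRB share climbs from 1.59% to 99.6%, while the shCON share lies between 76.2% and 99.1%.

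At the sites called in both lines the peak region was wider after RB depletion. Among 9712 sites where 1 shRB peak met 1 shCON peak, the median width was 701 bp (interval 695 to 707) in shRB and 364 bp (361 to 368) in shCON. The shRB peak was the wider at 9234 of these sites, or 95.1% (94.6 to 95.5), with a median difference of 273 bp (269 to 279). The shCON peak lay wholly inside its shRB partner at 79.7% (78.9 to 80.5) of sites, and the centres were a median of 66 bp apart. The order of sites by score was related between the lines, with a Spearman rho of 0.70 across sites, which are not independent replicates. Single-line peaks were narrow in both lists: the median width was 317 bp (314 to 320) for shRB-only peaks and 245 bp (240 to 250) for shCON-only peaks. Width rises with the depth and enrichment of a library, and neither is known here.

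**Figure D2:**
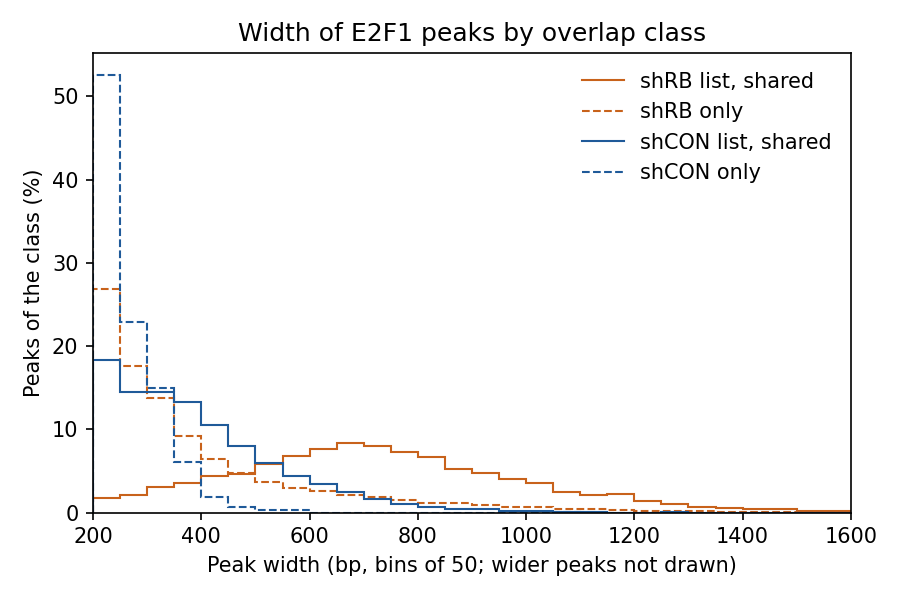
Distribution of peak width (bp, in bins of 50 bp) as a percentage of each overlap class, for shared (solid) and single-line (dashed) peaks of the shRB list (orange) and the shCON list (blue). Shared shRB peaks centre near their median of 712 bp, and the other 3 classes have medians of 359 bp (shared shCON), 317 bp (shRB only) and 245 bp (shCON only).

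The strongest sites were common to both lines. The highest-scoring shRB peak lay on chromosome 15 (hg19, 40452976 to 40453606), with a score of 355, and its shCON partner ranked 13th of that list. The next lay on chromosome 19 (33462687 to 33463331, score 333), where the shCON partner ranked 3rd. The others were on chromosome 1 (46713168 to 46713670, score 328), chromosome 8 (27694976 to 27695665, score 328) and chromosome 1 (156542026 to 156542631, score 327). Their shCON partners ranked 9th, 14th and 21st. At each of these 5 sites the shRB peak was the wider, for example 631 bp against 547 bp on chromosome 15.

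The strongest shRB-only peak lay on chromosome 1 (142618631 to 142619149). It had a score of 151, ranked 896th in the list and lay 13.3 kb from the nearest shCON peak. It also lay within 1 Mb of the longest stretch without peaks on that chromosome, from 121485507 to 142582240. The next were on chromosome 6 (139695461 to 139696056, score 129), chromosome 17 (73774925 to 73776055, score 117), chromosome 8 (59323676 to 59324205, score 109) and chromosome 10 (5488370 to 5488779, score 105). Their distances to the nearest shCON peak were 0.465 kb, 4.58 kb, 141 kb and 19.8 kb. The chromosome 6 peak gained a partner when shCON peaks were extended by 500 bp. The strongest shCON-only peak lay on chromosome 2 (158866757 to 158867135), with a score of 70.8, rank 697 and a distance of 133 kb to the nearest shRB peak. It was followed by peaks on chromosome 10 (43136273 to 43136657, score 69.8), chromosome 11 (75206524 to 75206876, score 65.6, and 82798149 to 82798523, score 65.5) and chromosome 12 (48565275 to 48565661, score 63.6). The chromosome 10 peak lay 1.94 kb from a shRB peak and within 1 Mb of the longest stretch without peaks on that chromosome, from 38817951 to 42360697, and the last 3 lay 18.2 kb, 14.8 kb and 11.6 kb away.

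Most shRB-only sites were separate from the shared ones, though nearer to them than chance placement gave. The placement was uniform over each chromosome's span, stretches without peaks included. It therefore cannot tell closeness to shared peaks from both classes lying in the same peak-rich regions. The median distance from a shRB-only peak to the nearest shared peak was 59.6 kb (interval 57.9 to 61.4), against a mean of 168 kb over 100 random placements, which ranged from 160 to 176 kb. Within 1 kb of a shared peak lay 5.94% (5.59 to 6.32) of shRB-only peaks, against 1.30% of placed ones. Within 5 kb the shares were 10.0% (9.57 to 10.5) and 4.45%. Counted in windows of 1 Mb, 2617 windows held a shRB peak and 2227 a shCON peak. A shRB peak with no shCON peak was found in 422 windows, which held 1098 shRB peaks, and the reverse in 32 windows. The windows richest in shRB-only peaks, picked after their values were seen, were on chromosome 19 (1000001 to 2000000, with 38 of 74 shRB peaks) and chromosome 16 (1 to 1000000, with 36 of 58). Both were also rich in shCON peaks, with 39 and 22, and held fewer shRB-only peaks than the 46.2 and 39.8 expected from the scores. The largest excess over that expectation was on chromosome 5 (141000001 to 142000000), with 21 shRB-only peaks against 16.0 expected. This window was picked on that same excess among 2649 windows with a peak in either list. Some excess therefore follows from the picking, and it was not tested.

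Among chromosomes 1 to 22 and X, E2F1 peaks were densest on chromosome 19, the most gene-rich human chromosome, in both lines. There were 28.9 shRB and 15.2 shCON peaks per Mb on chromosome 19, and 20.3 and 8.51 on chromosome 22. Chromosome X had the lowest density of this set in both lists, at 4.05 and 1.49 per Mb. The ratio of shRB to shCON peaks was 1.90 (1.75 to 2.06) on chromosome 19, 1.91 (1.75 to 2.09) on chromosome 3 and 3.32 (2.68 to 4.11) on chromosome 21. The other chromosomes of this set lay between these values. The shRB-only share of shRB peaks was 50.1% (47.7 to 52.5) on chromosome 19 and 74.5% (69.8 to 78.7) on chromosome 21, against 61.6% over the whole list. From the scores of their peaks alone, 56.9% was expected on chromosome 19 and 68.2% on chromosome 21. On chromosomes 6 and 7 the observed shares were 2.65 and 2.90 percentage points above the expected ones, which also lay outside the intervals; with 50 score bins the difference on chromosome 6 was 2.47 points and its expected share fell inside the interval. On the other 19 of these 23 chromosomes the expected value fell within the interval. At the interval's nominal level, 1.15 of all 23 would fall outside by chance. The Wilson interval does not allow for the scores, on which the expected value already rests. It is therefore too wide for this comparison, and an expected value inside it is only weak evidence of agreement.

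**Figure D3:**
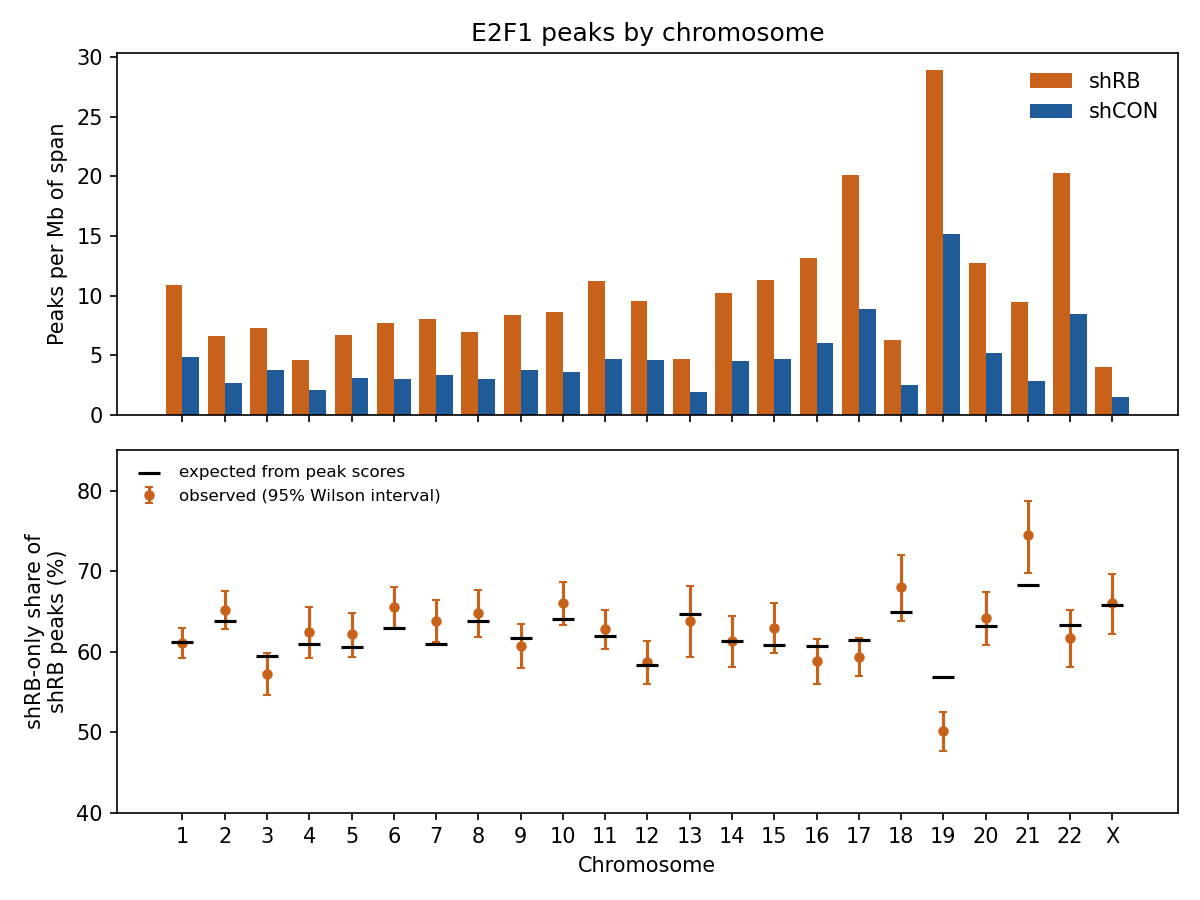
Upper panel, shRB (orange) and shCON (blue) peaks per Mb on chromosomes 1 to 22 and X; lower panel, shRB-only share of shRB peaks (%) with 95% Wilson intervals, and the share expected from the peaks' score deciles (black bars; the axis does not start at 0). Chromosome 19 has 28.9 and 15.2 peaks per Mb and lies below its expected share, and chromosome 21 lies above it.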

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

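A smaller overlapping share in the shRB list than in the shCON list was kept in the alternatives run, while its size depended on the overlap rule and on list length. This direction largely follows from the longer shRB list, since overlapping peaks were similar in number, 10139 in shRB and 10527 in shCON. That it was kept is therefore no separate support. The longer shRB list was checked only by restricting to chromosomes 1 to 22 and X. The lower median scores of single-line than of shared peaks were checked only with the reciprocal overlap. Both directions were kept there. The shares of shRB and of shCON peaks with a partner, 38.4% and 90.3% as reported, were 40.2% and 91.9% with the upper 50% of each list, 76.7% and 80.0% with equal numbers from the top of each list, 22.9% and 52.0% with a reciprocal overlap of 50%, 33.0% and 74.9% with centres within 200 bp, and 40.5% and 91.0% with the other list extended by 500 bp. Equal numbers bring the shares together by construction, since the lists then have the same length. The gap that is left comes from peaks that overlap more than 1 peak of the other list. In the whole lists, 395 shRB and 17 shCON peaks did so. With the reciprocal rule the median scores were 75.3 for shared and 16.4 for single-line peaks of the shRB list, and 18.9 and 9.03 in the shCON list. The share of shRB peaks on chromosome 19 was 7.31% among the strongest 11653 against 6.43% in the whole list, and that on chromosome 21 was 1.13% against 1.38%. Restricting to chromosomes 1 to 22 and X left the shares and the ratio of peak numbers (2.27) within their intervals. So did an alternative added after the data were seen, leaving out peaks beside the longest peak-free stretches and those on chromosomes M and Y, for both shares (38.3% and 90.8%). Of the 10 named single-line peaks, 1 gained a partner under a looser rule. The upper 50% and equal numbers fix the ratio of peak numbers, so they gave no value for it, and the alternatives for promoters, genes and motifs were not run. Depth is unknown and limits what a missing peak means: a site without a call in shCON was not called there, which is not absence of binding.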

Other observations

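The shCON-only peaks were narrower than shared peaks of similar score, and the shRB-only peaks were narrower in the fifth to ninth score deciles. In the shCON list the difference in median width, averaged over the lowest 9 score deciles, was -62.6 bp (bootstrap interval -65.1 to -55.5), and it was negative in each of these 9 deciles. In the shRB list the differences were -31 to -149 bp in the fifth to ninth deciles and -11 to 13.5 bp in the lowest 4, which hold most shRB-only peaks. The windows of 1 Mb richest in shCON-only peaks were on chromosome 16 (46000001 to 47000000, 11 of 22 shCON peaks), chromosome Y (13000001 to 14000000, 10 of 12), chromosome 10 (42000001 to 43000000, 9 of 20), chromosome 2 (92000001 to 93000000, 7 of 12) and chromosome 4 (49000001 to 50000000, 7 of 11). Together these 5 windows held 44 of the 1126 shCON-only peaks, or 3.91%. The windows on chromosomes 16 and 10 held the end of their chromosome's longest peak-free stretch, at 46385923 and 42360697. On chromosomes 2, 4 and Y the longest such stretch lay elsewhere. Repeats were not mapped in any of these windows, so their shCON-only peaks need not be sites bound only in the control line.

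All of the tests below were chosen after the patterns they bear on had been seen. The values measured by the tests of sensitivity, spreading, calling threshold, near misses and copy number were also known at least in part by then, whereas those of repeats and of chromosome scores had not been computed.

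The 16292 shRB-only peaks may come from a lower detection sensitivity in the shCON library, from RB depletion, or from both. Spreading of the shared peaks into neighbouring sequence is argued against as the main source, since 5.94% (5.59 to 6.32) of shRB-only peaks lay within 1 kb of a shared peak. A lower sensitivity in shCON requires that strong shRB peaks be kept in shCON, and 0.378% (0.206 to 0.695) of the top decile was missing there, with the missing share falling at each step of score. A general gain of E2F1 binding after RB depletion would give the same relation, so this value does not separate them. With 1 library per line and no read depth, the effect of the knockdown stays open.

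The 1126 shCON-only peaks, sites called in the control line and not after RB depletion, were mostly low in score: 57.8% (54.9 to 60.7) lay in the lowest 3 score deciles, where 30% of the list lies. Some may be calls near the threshold, but the threshold is not given, and these deciles run from a score of 2.15 to 8.65. In each of them, 76.2% to 84.8% of shCON peaks were also found in shRB, so a low score alone does not set the shCON-only peaks apart. Repeats beside assembly gaps were a second candidate source. Within 1 Mb of the longest peak-free stretch of a chromosome, or on chromosome M or Y, lay 6.48% (5.19 to 8.07) of them, against 1.99% (1.75 to 2.26) of the whole shCON list. Counting each of the 92 peak-free stretches of at least 2 Mb raised this to 11.8% (10.1 to 13.8), against 3.78% of shared shCON peaks. Sites beside such stretches were thus over-represented, and most shCON-only peaks lay elsewhere. Assembly gaps and repeats themselves were not mapped here, and a peak-free stretch need not be a gap. Repeats away from these stretches were not counted, so the share of shCON-only peaks that lies in repeats stays open. For the 76 shCON-only peaks in the upper 25% by score, boundaries that just miss a shRB peak are argued against, since 7.89% (3.67 to 16.2) lay within 500 bp of one. Of these 76 peaks, 10.5% (5.43 to 19.4) lay beside the longest peak-free stretches or on chromosome M or Y, against 2.75% (2.21 to 3.42) of shared peaks in the same score range, and 18.4% (11.3 to 28.6) lay beside any stretch of at least 2 Mb or on chromosome M or Y. Loss of E2F1 from the remaining sites in shRB was not tested.

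The low shRB-only share on chromosome 19 and the high share on chromosome 21 are only in part accounted for by peak score. After allowing for score deciles the share was 6.28 percentage points above expectation on chromosome 21 (interval 1.57 to 10.5) and -6.78 points from it on chromosome 19. With 50 score bins the values were 6.02 and -6.94, and with score and width deciles together 6.26 and -7.25. A difference in peak score is thus argued against as the whole cause. More copies of chromosome 19 in the shCON line would raise the shCON-only share there, and that share was 2.35% (1.54 to 3.57) against 8.97% expected from score, a difference of -6.62 points. The shCON-only share also differed from its expectation by -3.92 points on chromosome 17, -4.46 on chromosome 22 and -6.30 on chromosome X. It lay above expectation by 4.05 points on chromosome 3, 4.28 on 4, 3.86 on 5, 4.42 on 8, 5.15 on 10 and 4.79 on 18. On all of these chromosomes the expected shRB-only share was within the interval of the observed one, which is only weak evidence of agreement. The shRB-only differences had the sign of the shCON-only ones on chromosomes 4, 5, 8, 10, 17, 18 and 22, as on chromosome 19. They ran from -2.13 points on chromosome 17 to 3.11 on chromosome 18. On chromosomes 3 and X the signs were opposite, with shRB-only differences of -2.20 and 0.239 points. Score alone thus does not set the value for no change, and a difference in copy number between the lines stays open. Base composition bias between the libraries and the kind of site gained after RB depletion could also shape these shares, and neither was tested.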
